A study of Rattus norvegicus with 16 samples.

How the data were processed

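RNA from the lateral cortex around a contusion was measured on 16 Affymetrix whole-genome rat arrays. Male Wistar rats had received a craniectomy 48 h before either a moderate lateral fluid percussion (a pressure pulse against the dura that bruises the cortex) or a sham procedure, and the brains were perfused with saline before dissection. Tissue was taken 3, 6, 12 or 48 h later. Injured animals gave 3 arrays at each time, and shams gave 1 array at each time. The labels give each array a number of its own, which was read as 1 animal per array. They do not say whether arrays share animals or processing days. Each array was treated as an independent replicate, and p-values of genes measure the spread between arrays. P-values of lists set the genes of a list against all other genes, given a correlation between genes. The study's own description groups the 3, 6 and 12 h shams as 1 control group of 3 arrays and keeps the 48 h sham apart, as the control for the 48 h injury.

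The deposited values are RMA log intensities per the submitters' processing notes (background correction, quantile normalization and summary of each probe set), here taken as log2, since the base is not stated. Each of the 31099 probe sets has its median over the 16 arrays subtracted in the deposited table. Every median was checked to be 0, and values run from -5.64 to 5.98 with 2 decimals. Differences between arrays can therefore be read, but not how strongly a gene is expressed or whether it is detected. No read depth exists for arrays, and the number of arrays limits the precision.

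Of the probe sets, 57 are array controls, 21268 are listed with a gene and 9780 with none. The 20832 probe sets with exactly 1 gene symbol were used, and the 436 with several symbols were left out. Symbols were updated through the gene identifier for 20764 probe sets, and 68 kept the symbol of the table. Probe sets of a gene were averaged, which gave 14218 genes, 9692 of them from 1 probe set and 4526 from more. Before the data were examined, the probe set with the highest mean had been chosen to stand for a gene. Centred values hold no such mean in a useful sense, so the mean of all probe sets, also written down at that time, was used in its place. That exchange was made after the data were seen, and the rule of the highest mean was kept as an alternative.

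Groups were compared with limma 3.58.1 in R 4.3.3. A single linear model of the 6 groups, with 10 residual degrees of freedom, gave each gene's log2 difference, its standard error (SE) and a moderated test. P-values were adjusted over the 14218 genes by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The comparisons were injury against sham at 3, 6, 12 and 48 h, the 48 h sham against the earlier shams, the steps between times in injured animals, and injury averaged over 3, 6 and 12 h with time as a factor in 12 arrays. In the 48 h comparison the lone sham was assumed to vary like the other groups. Injury at 48 h was also compared with the 3 earlier shams, a choice written down before the data were seen. On simulated data of 14218 genes, the test recovered 100%, 98%, 98% and 92% of 100 genes changed by a log2 of 1 at 3, 6, 12 and 48 h. These genes were drawn at random with each gene's own spread, beside 100 more changed by a log2 of 2. Genes with a wider spread need larger changes. The simulated 48 h test called 198 genes, which eases the adjustment of p-values, whereas the real one called 0. In the real data Lcn2 did not pass at 48 h at 3.83 ± 0.64, nor did Idi1 with a fall of nearly 1. The 92% therefore cannot be carried over to the real 48 h comparison.

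Before the data were examined, 37 lists were written down, 21 of pathways and 16 of cell type markers. They were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjusted p-values for lists cover 148 tests, the 37 lists in the 4 comparisons of injury with sham. List tests of the other steps form a second family and those of the 48 h injury against the earlier shams form another, both added after the data were seen. For the lists described, the number of called genes is given over all genes and adjusted over the list alone, as a range where several lists are described together.

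Genes named were set by a rule written before the data were examined. They are the called genes whose groups do not overlap with the largest changes (up to 8 higher and 6 lower in the first 3 comparisons with sham, up to 4 each way in the others), up to 2 called members of each called list, and a fixed panel of genes. Other list members, such as those of the endothelial list, were chosen after their values were seen.

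Alternatives were the other probe set rule, every probe set tested by itself, quantile normalization, median centring, a 2-fold minimum, only the arrays of the groups compared in the model, other choices of sham, leaving out each array in turn, and a block for arrays of the same replicate number. A test of the difference between the 12 and 48 h effects was also run. Added after the data were seen were fits without the arrays highest in Ttr, fits without the 2 arrays with the widest spread, robust eBayes, and the averaged comparison without each injured array. A filter on dim genes, an intensity trend in eBayes and a mean of linear values need levels and were not run.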

Results

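Gene expression was measured in the injured lateral cortex of rats at 4 times after fluid percussion (3, 6, 12 and 48 h), with 3 arrays per time, and in sham animals with 1 array per time. The design asks how the cortex responds over the first 2 days. For 14218 genes, changes are given as log2 differences with the SE, 3 injured arrays against the 3 shams of 3, 6 and 12 h unless another control is named. No 2 arrays were duplicates, since the closest pair differed by a root mean square of 0.202. The spread over genes was widest in injured 48 h replicate 2 (SD 0.387) and injured 12 h replicate 2 (SD 0.372). In that 12 h array the polyA spike-in controls averaged -1.69 (24 probe sets) while its hybridization controls averaged -0.09.

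At 3 h the cortex had switched on signals that recruit leukocytes. Ccl2, which attracts monocytes, rose 50.8-fold (log2 5.67 ± 0.76, adjusted p = 0.0025), Ccl3 rose by 5.19 ± 0.31 (adjusted p = 7.94e-07) and Ccl4 by 4.71 ± 0.27. The interleukin genes Il1b (5.14 ± 0.39), Il1a (5.10 ± 0.30) and Il6 (3.15 ± 0.29) rose together with Cxcl2 (4.79 ± 0.45) and Cxcl1 (3.79 ± 0.58), which attract neutrophils. Tnfaip3, a feedback inhibitor of NF-kB signalling, rose by 2.72 ± 0.23, the survival gene Bcl2a1 by 3.14 ± 0.33, and the leukocyte adhesion gene Icam1 by 3.00 ± 0.22. Among genes that fell, the collagen gene Col1a2 changed by -1.997 ± 0.37 (adjusted p = 0.0249), Serping1, which inhibits complement C1, by -1.51 ± 0.28, and Cavin2, a part of membrane caveolae, by -1.50 ± 0.21. Ada, which breaks down adenosine, fell by 1.10 ± 0.21, the transcriptional regulator Id3 by 1.03 ± 0.16, and the Wnt antagonist Shisa3 by 1.13 ± 0.21. In each of these genes all 3 injured arrays lay on 1 side of all 3 shams, which the rule for naming genes required of most of them.

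In total 69 genes were higher and 14 lower at 3 h. Leaving out an array moved the total of 83 by more than 1.5 times in 4 cases, to 33 without injured replicate 2, 39 without injured replicate 3, 38 without the 6 h sham and 33 without the 12 h sham. Without the 3 h sham the total was 117, of which 51 were lower. In these 6 fits Atf3 was called in 0 (adjusted p up to 0.25), Serping1, Ada and Idi1 in 1 each (up to 0.16) and Col1a2 and Shisa3 in 2 each (up to 0.14). Id3 was lost without injured replicate 2 or the 12 h sham (up to 0.063). With the single 3 h sham as control 13 genes were called, with only the 2 groups in the fit 151, and with quantile normalization 199.

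Of the lists, cytokines and chemokines had the largest median change at 3 h. It was 1.96 over 20 measured genes, 10 of them higher over all genes and 12 adjusted over the list alone (adjusted p = 0.0186 with an estimated correlation). Immediate early genes, which neurons and glia transcribe within minutes of a stimulus, had a median of 1.002, with 5 of 16 higher and 14 adjusted over the list alone (0.0186 with an estimated correlation). Ier3 rose by 2.37 ± 0.30, Atf3 by 2.28 ± 0.47 (adjusted p = 0.048) and Fos by 1.29 ± 0.17, though the 2 probe sets of Fos gave -0.15 and 2.73. NF-kB targets had 7 of 12 genes higher, 8 adjusted over the list alone (median 0.86, adjusted p = 0.0186 with an estimated correlation). These 3 were the lists whose calls held with an estimated correlation at 3 h, of 13 called.

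The other 10 lists called at 3 h were lost with an estimated correlation. Activated endothelium, led by Icam1, had a median of 0.23 with 1 of 10 genes higher and 3 adjusted over the list alone (adjusted p = 0.062 with an estimated correlation). Oligodendrocyte markers had a median of 0.39 (0 of 15 higher, 4 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Cholesterol synthesis had a median of 0.21, with Idi1 higher by 0.63 ± 0.12 (3 adjusted over the list alone, adjusted p = 0.087 with an estimated correlation). Meninges and fibroblast markers had a median of -0.48, with Col1a2 lower and 7 adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Interferon response (Irf1 rose by 2.29 ± 0.34), heat shock, endoplasmic reticulum stress, apoptosis, choroid plexus, and erythrocyte lists had medians from 0.04 to 0.16, with 0 or 1 gene higher each, 1 or 2 adjusted over the list alone, and adjusted p from 0.06 to 0.56 with an estimated correlation. The haemoglobin gene Hbb rose by 3.40 ± 0.52, and Ttr, a choroid plexus gene, lay 5.24 and 6.06 above the shams in injured replicates 2 and 3 and 1.43 in replicate 1.

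**Figure D1:**
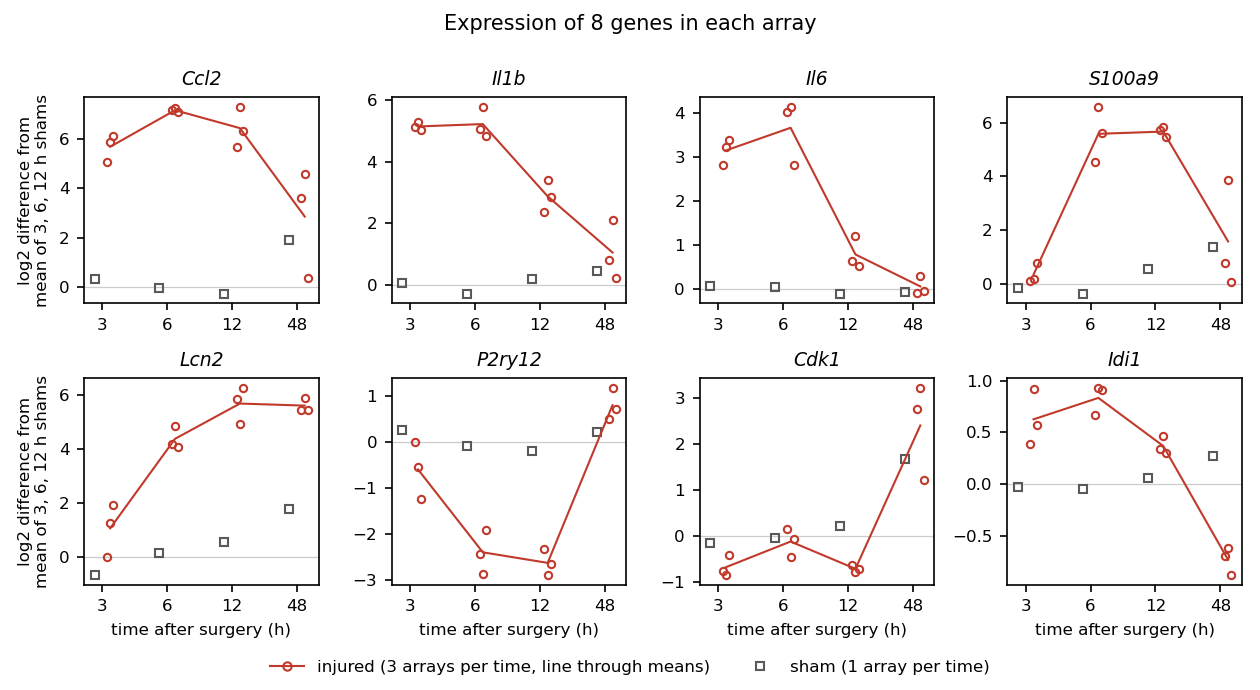
Log2 difference of 8 genes in each array from the mean of the 3, 6 and 12 h shams. Hours on the axis, labelled time after surgery, count from the percussion or sham procedure and not from the craniectomy. Injured arrays are circles with a line through their means, and shams are squares. Il6 lay between 0.53 and 1.21 in the injured 12 h arrays and Lcn2 between 5.47 and 5.92 in the injured 48 h arrays. The 48 h sham itself lay at least 1.37 above the mean of the earlier shams for Ccl2, Lcn2, S100a9 and Cdk1.

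At 6 h the largest rises were in Ccl2 and the neutrophil gene S100a9. Ccl2 reached 141-fold (log2 7.14 ± 0.76, adjusted p = 0.000163). S100a9 and S100a8, which encode the neutrophil protein calprotectin, rose by 5.58 ± 0.73 and 4.17 ± 0.53, and Lcn2, which binds iron carriers of bacteria, by 4.38 ± 0.45. Sele, the endothelial adhesion molecule that slows leukocytes, rose by 4.51 ± 0.70, the interferon-induced GTPase gene Gbp2 by 4.68 ± 0.53 and the T cell chemokine Cxcl10 by 4.43 ± 0.64. P2ry12, the purine receptor of resting microglia, fell 5.25-fold (log2 -2.39 ± 0.30, adjusted p = 0.00047) and Gpr34, also a microglial receptor, changed by -1.48 ± 0.21. Slco1a4 and Abcg2, transporter genes of brain vessels, fell by 1.91 ± 0.46 and 1.77 ± 0.39, as did the collagens Col3a1 (-2.14 ± 0.48) and Col1a2 (-1.93 ± 0.37) and the tetraspanin Tspan8 (-1.92 ± 0.31). All 3 injured arrays lay outside the range of the 3 shams for each of these genes, which the naming rule again required of most of them.

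In total 282 genes were higher and 97 lower at 6 h. The total of 379 moved to 225 without injured replicate 1, 177 without injured replicate 2, 242 without the 3 h sham, 202 without the 6 h sham and 229 without the 12 h sham. Slco1a4 was called in 0 of the fits that leave out 1 array (adjusted p up to 0.15), Gadd45b in 1 (up to 0.093), Abcg2 and Col3a1 in 2 each (up to 0.14) and Col1a2 in 3 (up to 0.065) of 6. Quantile normalization of the deposited values gave 921, only the 2 groups in the fit 796, and the single 6 h sham as control 75.

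Among lists at 6 h, cytokines and chemokines had 12 of 20 genes higher (16 adjusted over the list alone, median 2.49) and NF-kB targets 10 of 12 (11 adjusted over the list alone, median 1), each at an adjusted p of 0.0186 with an estimated correlation. Interferon response genes had 10 of 19 higher (14 adjusted over the list alone, median 0.97, adjusted p = 0.0186 with an estimated correlation), with Irf1 at 2.85 ± 0.34. Activated endothelium had 3 of 10 higher (6 adjusted over the list alone, median 0.50, adjusted p = 0.0267 with an estimated correlation). These 4 calls of 20 held with an estimated correlation.

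Reactive astrocyte genes had a median of 1.27 at 6 h, with 8 of 17 higher and 11 adjusted over the list alone, and a call lost at an adjusted p of 0.0826 with an estimated correlation. Neutrophil genes had 3 of 9 higher (5 adjusted over the list alone, adjusted p = 0.087 with an estimated correlation), with Hbb at 3.88 above the shams in the same arrays. Microglia markers had 3 of 12 lower (4 adjusted over the list alone, median -0.36, adjusted p = 0.48 with an estimated correlation). Apoptosis and p53 targets had 8 of 18 higher (9 adjusted over the list alone, adjusted p = 0.064 with an estimated correlation), among them Gadd45b at 2.17 ± 0.46. The chaperone genes Hspb1 (2.92 ± 0.53) and Hspa1a (1.68 ± 0.29) rose in the heat shock list (2 of 13 higher, 3 adjusted over the list alone), lost at an adjusted p of 0.32 with an estimated correlation. Cholesterol synthesis had 3 of 13 higher (9 adjusted over the list alone, adjusted p = 0.0826 with an estimated correlation), with Idi1 at 0.83 ± 0.12. The remaining 10 called lists, which include monocyte genes (Cd14, 3.54 ± 0.61) and matrix genes (Adamts1, 3.14 ± 0.45), had 0 to 6 genes called in the direction of the list, 0 to 8 adjusted over the list alone, and adjusted p from 0.18 to 0.58 with an estimated correlation.

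At 12 h the largest rises were in Ccl2, Lcn2 and S100a9. Ccl2 was 85.6-fold higher (log2 6.42 ± 0.76, adjusted p = 0.000324), and Lcn2 reached 5.69 ± 0.45 and S100a9 5.67 ± 0.73. The antiviral gene Rsad2 rose by 3.39 ± 0.30, Cxcl10 by 4.62 ± 0.64, the protease inhibitor gene Slpi by 4.49 ± 0.62, the monocyte chemokine Ccl7 by 4.53 ± 0.51 and the chaperone gene Hspb1 by 4.35 ± 0.53. Gfap, the astrocyte filament gene, rose by 1.16 ± 0.24 (adjusted p = 0.0123) and Hmox1, which degrades haem, by 2.90 ± 0.63. P2ry12 was lower by -2.62 ± 0.30 and Gpr34 by -1.65 ± 0.21. The gap junction gene Gjb6 of astrocytes changed by -1.14 ± 0.19, and the neuronal kinase gene Camk2a by -0.69 ± 0.12 (adjusted p = 0.0054). Abcg2 (-2.15 ± 0.39), the stem cell marker Prom1 (-1.59 ± 0.29) and Ogn, a proteoglycan of the meninges (-1.63 ± 0.37), also fell.

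In total 496 genes were higher and 196 lower at 12 h. The total of 692 moved to 1230 without injured replicate 3, which was also the 12 h array highest in Ttr. With the single 12 h sham as control it was 91, and with only the 2 groups in the fit 271. Without injured replicate 2, the array with low spike-in signal, it was 324, without the 3 h sham 403 and without the 6 h sham 287. Gfap was not called without injured replicate 2 or the 6 h sham (adjusted p up to 0.065), nor Hmox1 and Ogn without these or the 12 h sham (up to 0.11). Grm3 was lost without injured replicate 2 or the 3 or 6 h sham (up to 0.064), and Aldh1l1 without the 3 or the 6 h sham (up to 0.09). RT1-Da, Cd74 and Pvalb were called in 1 of these 6 fits each (up to 0.21).

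Interferon response was the list whose call held with an estimated correlation at 12 h, of 19 called. It had 13 of 19 genes higher and 15 adjusted over the list alone (median 1.25, adjusted p = 0.0186 with an estimated correlation). Reactive astrocyte genes had 12 of 17 higher, 13 adjusted over the list alone (median 1.68, adjusted p = 0.06 with an estimated correlation). Cytokines and chemokines had 11 of 20 higher, 15 adjusted over the list alone (median 1.07, adjusted p = 0.06 with an estimated correlation). Complement and antigen presentation had 8 of 16 higher, 9 adjusted over the list alone (adjusted p = 0.25 with an estimated correlation), with the class II genes RT1-Da (1.81 ± 0.46) and Cd74 (1.57 ± 0.42). Neutrophil genes had 4 of 9 higher, 5 adjusted over the list alone (adjusted p = 0.087 with an estimated correlation), with Hbb at 2.53 above the shams.

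The lists called lower at 12 h included neuronal and glial markers. Glutamate and GABA receptors had 1 of 17 lower and 4 adjusted over the list alone (median -0.25, adjusted p = 0.18 with an estimated correlation), with the metabotropic receptor gene Grm3 at -0.61 ± 0.13. Neuron markers had 2 of 18 lower, both also adjusted over the list alone (median -0.18, adjusted p = 0.36 with an estimated correlation), namely Camk2a and the interneuron gene Pvalb (-0.37 ± 0.09). Astrocyte markers had 3 of 14 lower, 4 adjusted over the list alone (adjusted p = 0.1 with an estimated correlation), including Aldh1l1 (-0.50 ± 0.11). Meninges and fibroblast markers had 4 of 13 lower, 7 adjusted over the list alone (adjusted p = 0.32 with an estimated correlation), and oxidative phosphorylation had a median of -0.07 with 0 of 17 called and 0 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). The other 9 called lists were higher, with 2 to 8 genes called, 3 to 10 adjusted over the list alone, and adjusted p from 0.087 to 0.36 with an estimated correlation.

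**Figure D2:**
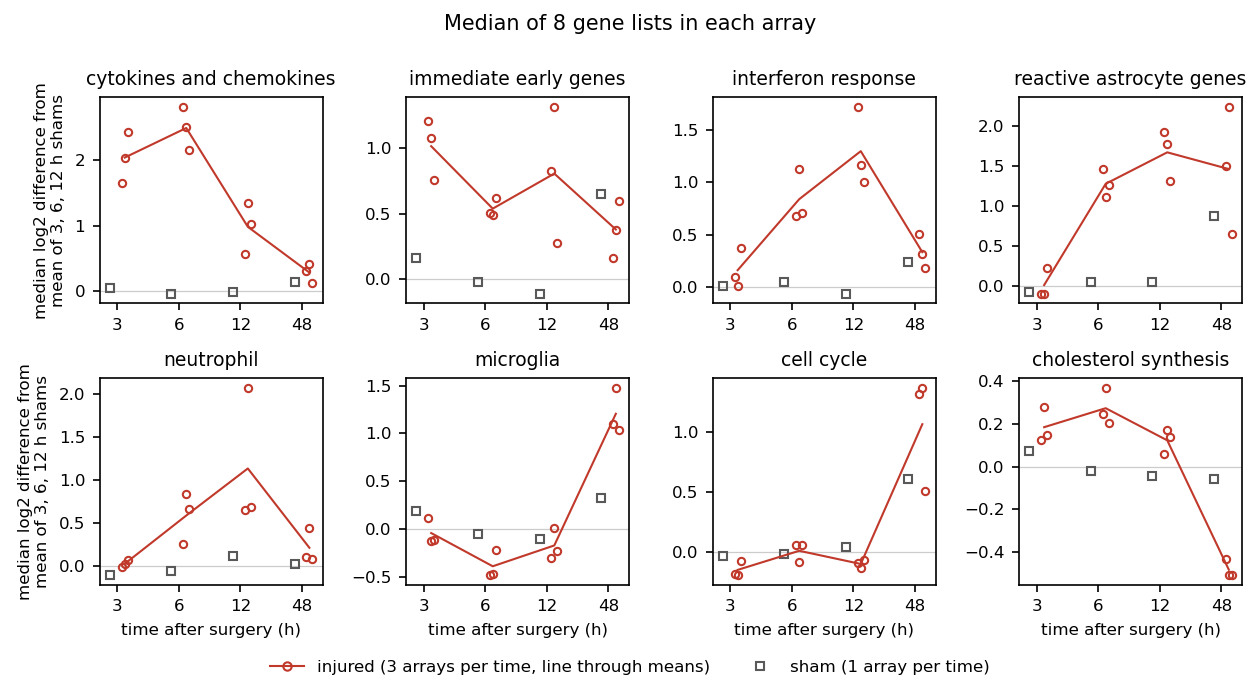
Median log2 difference of 8 gene lists in each array from the mean of the 3, 6 and 12 h shams. Hours on the axis, labelled time after surgery, count from the percussion or sham procedure and not from the craniectomy. Injured arrays are circles with a line through their means, and shams are squares. Cholesterol synthesis genes lay between -0.51 and -0.43 in the injured 48 h arrays and at -0.06 in the 48 h sham.

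Called genes were shared between times. Of the 69 genes higher at 3 h, 55 were also higher at 6 h, against 1.37 for independent lists, and 228 were higher at both 6 and 12 h, against 9.84. At all of 3, 6 and 12 h 41 genes were higher, Ccl2, Il1b and Icam1 among them, and 7 were lower, such as Col1a2. Log2 changes correlated across genes at 0.64 between 3 and 6 h, 0.85 between 6 and 12 h and 0.44 between 3 and 12 h. In simulated data with the same shared controls and no injury effect the correlation was 0.50, so the value for 3 and 12 h lay below it. Covariances of the log2 changes were 0.0513, 0.0942 and 0.0376 for these pairs, each above the 0.0092 of the simulated data. In those data 0 higher genes were shared, but without an injury effect hardly any gene can be called. That count therefore does not measure how many called genes are shared through the common shams. Genes are not independent replicates.

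Averaged over 3, 6 and 12 h, Ccl2 (6.41 ± 0.36), Il1b (4.41 ± 0.42), Ccl3 (4.09 ± 0.43) and Cxcl10 (4.04 ± 0.62) had the largest rises. The largest falls were in Lbp, which binds bacterial lipopolysaccharide (-2.14 ± 0.26), P2ry12 (-1.87 ± 0.32), Col1a2 (-1.83 ± 0.25) and Col3a1 (-1.81 ± 0.35). With time as a factor in 12 arrays, 203 genes were higher and 70 lower. The total of 273 moved to 448 without the 3 h sham, 62 without the 6 h sham and 88 without the 12 h sham, and Cxcl10, Col3a1 and P2ry12 were not called without the 6 h or the 12 h sham (adjusted p up to 0.27).

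From 3 to 6 h in injured cortex the neutrophil genes S100a9 and S100a8 had the largest rises and the interleukin gene Il1a the largest fall. S100a9 rose 37.7-fold (log2 5.24 ± 0.73, adjusted p = 0.00396), S100a8 by 4.15 ± 0.53, the decoy receptor gene Il1r2 by 3.35 ± 0.50 and Lcn2 by 3.32 ± 0.45. Il1a fell by 2.76 ± 0.30, P2ry12 by 1.80 ± 0.30, Prom1 by 1.75 ± 0.29 and the scavenger receptor gene Olr1 by 1.52 ± 0.21. There were 113 genes higher and 57 lower. The total of 170 moved to 42 without injured 3 h replicate 1, 51 without 3 h replicate 2, 87 without 6 h replicate 1, 39 without 6 h replicate 2 and 76 without 6 h replicate 3. P2ry12 was lost without 3 h replicate 1, 3 h replicate 2 or 6 h replicate 2 (adjusted p up to 0.064), and Prom1 without 6 h replicate 2 (0.054). Of 37 lists 13 were called, and none held with an estimated correlation, where the interferon response (median 0.60, 5 of 19 higher, 10 adjusted over the list alone) had an adjusted p of 0.16 and reactive astrocyte genes (median 1.24, 6 of 17 higher, 13 adjusted over the list alone) 0.23.

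Between 6 and 12 h only Il6 (-2.88 ± 0.29, adjusted p = 0.00157) and Ccl4 (-2.26 ± 0.27, adjusted p = 0.00539) passed the threshold, and both fell. With limma, 0 genes were called higher, and 1249 genes had an unadjusted p under 0.05, against 711 from chance. The small count therefore does not show that the other genes stayed the same. The total of 2 was 1 without 6 h replicate 2, where Ccl4 was lost (adjusted p = 0.062), 5 without 6 h replicate 3, 11 without 12 h replicate 2 and 45 without 12 h replicate 3. Of the lists 9 were called, and none held with an estimated correlation, with cytokines and chemokines (median -0.32, 2 of 20 lower, 7 adjusted over the list alone) at an adjusted p of 0.28.

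At 48 h no gene passed the test against the lone 48 h sham. With limma 0 genes were higher and 0 lower, while 1061 had an unadjusted p under 0.05, against 711 from chance. Lcn2 was 14.2-fold higher (log2 3.83 ± 0.64, adjusted p = 0.12) and the microglial receptor gene Trem2 had a difference of 1.79 (adjusted p = 0.051), neither of which passed. Ccl2 (0.94 ± 1.07) and Il1b (0.60 ± 0.55) differed by about their error and did not pass (adjusted p = 0.9 and 0.86). Without injured replicate 3 there were 129 genes, 112 higher and 17 lower, without replicate 1 there were 2 and without replicate 2 there was 1.

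Cholesterol synthesis genes were lower at 48 h as a group. All 13 measured members were negative, with a median of -0.43. Over all genes 0 of them were called with limma, and 10 were lower adjusted over the list alone (adjusted p = 0.0186 with an estimated correlation). Idi1, an enzyme of the isoprenoid step, had a difference of -0.997 ± 0.17 (adjusted p = 0.12). Of 12 lists called at 48 h this was the only call that held with an estimated correlation.

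The other 11 calls at 48 h were lost with an estimated correlation, and none had a member called over all genes. Microglia markers had a median of 0.83, with 7 of 12 higher adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). Complement and antigen presentation had a median of 0.65, 5 of 16 higher adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). Cell cycle genes had a median of 0.60, 2 of 19 higher adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Astrocyte markers were at 0.18 (adjusted p = 0.06 with an estimated correlation) and oligodendrocyte precursor markers at 0.17 (adjusted p = 0.23 with an estimated correlation). Immediate early genes had a median of -0.36 (adjusted p = 0.33 with an estimated correlation), which turned to 0.46 against the earlier shams and 0.23 against all 4 shams. Voltage-gated potassium channels were at -0.19 (adjusted p = 0.32 with an estimated correlation). These last 4 lists had 0 genes adjusted over the list alone. Reactive astrocyte, monocyte, neuron and oxidative phosphorylation lists had 0 to 2 genes adjusted over the list alone and adjusted p from 0.32 to 0.49 with an estimated correlation.

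The 48 h sham, a single array, was also compared with the 3 earlier shams. Alb, the albumin gene, was the 1 gene that fell (log2 -3.83 ± 0.44, adjusted p = 0.00861), and without the 6 h sham it no longer passed (adjusted p = 0.0521) and the count was 0. Without the 3 h sham the count was 2. In the 6-group limma fit 0 genes were called higher, and 973 had an unadjusted p under 0.05 in either direction. With only the groups compared in the fit 63 genes were higher and 7 lower, and with quantile normalization 21 and 8. Its immediate early genes (median 0.65), cell cycle genes (0.61), complement genes (0.90) and reactive astrocyte genes (0.87) lay above those of the earlier shams, with 0 genes higher in each over all genes and 5, 3, 5 and 5 adjusted over the list alone. All 11 list calls were lost with an estimated correlation, where these 4 had adjusted p of 0.23, 0.41, 0.41 and 0.56.

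Against the 3 earlier shams, 48 h of injury gave 905 genes higher and 472 lower. Lcn2 was 49.1-fold higher (log2 5.62 ± 0.45, adjusted p = 0.00011), followed by the macrophage genes Spp1 (4.35 ± 1.11) and Gpnmb (4.23 ± 0.50) and the Fc receptor-like gene Fcrl2 (4.31 ± 0.38). Insig1, which restrains sterol synthesis, was at -1.19 ± 0.18. Mfsd2a, a lipid carrier of brain vessels, was at -1.36 ± 0.26, Alb at -1.37 ± 0.31 and the muscle gene Tnnc2 at -1.44 ± 0.32. Cell cycle genes had 16 of 19 higher (18 adjusted over the list alone) and complement genes 13 of 16 (14 adjusted over the list alone), each with an adjusted p of 0.18 with an estimated correlation. Microglia markers had 9 of 12 higher (11 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis had 9 of 13 lower (11 adjusted over the list alone, adjusted p = 0.076 with an estimated correlation), and none of the 20 called lists held with an estimated correlation. Since time and control differ here, the effect of injury and of the later time are mixed.

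From 12 to 48 h in injured cortex the largest rises included the microglial gene P2ry12 and genes of dividing cells, and the largest falls a chemokine and neutrophil genes. Fcrl2 rose 24.5-fold (log2 4.62 ± 0.38, adjusted p = 2.3e-05), P2ry12 by 3.43 ± 0.30, the replication gene Pclaf by 3.22 ± 0.39 and Cdk1, the kinase that starts mitosis, by 3.12 ± 0.36. Cxcl10 fell by 4.37 ± 0.64, S100a9 by 4.09 ± 0.73, Il1r2 by 3.61 ± 0.50 and S100a8 by 3.57 ± 0.53. There were 1165 genes higher and 1015 lower. The total of 2180 moved to 1339 without 48 h replicate 1 and 1351 without 48 h replicate 2. It was 967 without the 2 arrays with the widest spread, 1260 with quantile normalization, 388 with only the 2 groups in the fit, and 29 as the difference of the injury effects. Of the 8 genes named here, that difference kept the call for Fcrl2 and P2ry12 and lost it for the other 6. The 48 h sham itself lay above the mean of the earlier shams, by 1.66 for Cdk1 and 2.30 for Pclaf. No sham enters the direct step, so injury and the later hour are mixed in it. Microglia markers had 10 of 12 higher (11 adjusted over the list alone, median 1.67, adjusted p = 0.23 with an estimated correlation) and cell cycle genes 14 of 19 (15 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation). Interferon response had 12 of 19 lower (13 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation) and cholesterol synthesis 10 of 13 lower (12 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). No list of the 14 called at this step held with an estimated correlation.

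**Figure D3:**
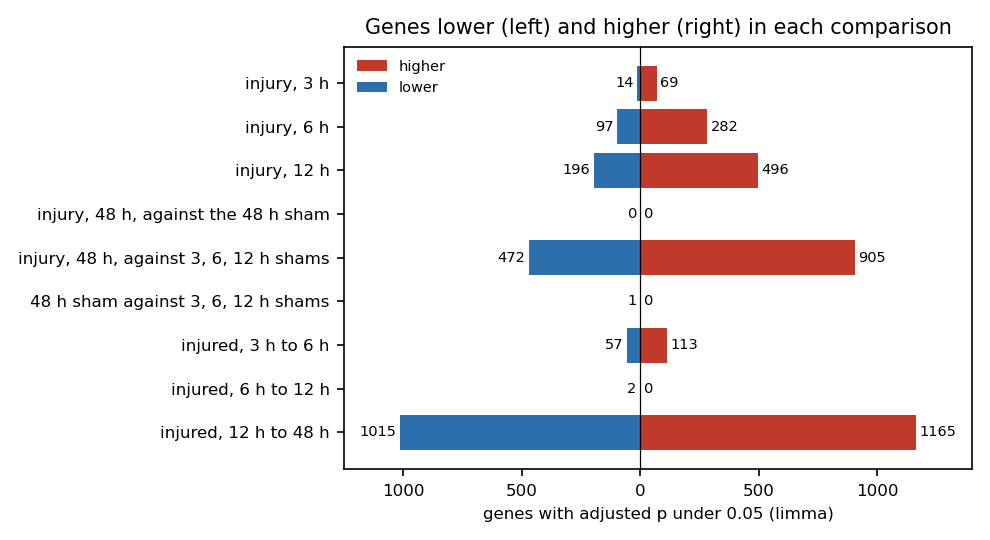
Number of genes lower (left) and higher (right) at an adjusted p under 0.05 in limma, for each comparison. Injury against sham gave 83, 379 and 692 genes at 3, 6 and 12 h and 0 against the 48 h sham, while 1377 were called at 48 h against the earlier shams.

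Lists for glucocorticoid-responsive genes, the circadian clock, neurotrophins and neuropeptides, reference genes, lymphocytes, endothelium, mural cells, striatum and skeletal muscle were called in none of the 4 comparisons of injury with sham. Reference genes had medians from -0.07 to 0.03 with 0 genes called by limma. Snap25, a gene of the synapse, had differences of 0.00 at 3 and 6 h, -0.04 at 12 h and -0.08 at 48 h, and Mbp, of myelin, had 0.11, 0.16, 0.15 and -0.12, none of which passed. The neurotrophin gene Bdnf, the GABA synthesis gene Gad1 and the water channel gene Aqp4 did not pass at any time either. In the lists called in these 4 comparisons the median, the mean and the test had the same sign, and among the lists not called they differed in 7, 3, 5 and 3 at 3, 6, 12 and 48 h.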

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

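The tests of the 48 h sham, with the rule that reads the injury-like gap against its spread, the range of Ttr within groups and the comparison of neutrophil genes with Hbb were chosen only after the results were seen, while the other splits of the arrays and the further choroid plexus genes were chosen before.

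The injury effect differed between times in a test of the difference itself. Between 3 and 6 h it differed for 170 genes, 113 toward higher, led by S100a9, and 57 toward lower, led by Il1a. Both effects share the same shams, so this equals the direct comparison of injured arrays and removes no effect of the hour itself. Between 6 and 12 h it differed for 2 genes, Il6 and Ccl4, where the same holds. Between 12 h, against the 3 earlier shams, and 48 h, against the 48 h sham, it differed for 29 genes. The 15 that turned toward higher include Fcrl2 (4.01 ± 0.66), the microglial genes P2ry12 (3.21 ± 0.51), Gpr34 (2.45 ± 0.37) and Trem2 (2.38 ± 0.29), and Alb (3.90 ± 0.54). The 14 that turned toward lower include the interferon genes Rsad2 (-3.20 ± 0.52), Irgm2 (-2.70 ± 0.42), Isg15 (-2.45 ± 0.35) and Irf7 (-1.75 ± 0.25), with Fos (-1.55 ± 0.29) and Idi1 (-1.37 ± 0.21). Alb was also the 1 gene called lower in the 48 h sham against the earlier shams, so that array carries its difference, while injured arrays changed by 0.08 from 12 to 48 h. For Fos too the 48 h sham lay 1.14 above the earlier shams, and injured arrays changed by -0.41.

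Probe sets without a listed gene, left out of the comparisons, also responded. Of 9780 such probe sets, 7 were called at 3 h (6 higher, 1 lower), 60 at 6 h (51 higher, 9 lower) and 103 at 12 h (79 higher, 24 lower). Against the 48 h sham 0 were called at 48 h, while 279 were called from 12 to 48 h in injured arrays. The control probe set for 5S ribosomal RNA reached 1.73 in injured 48 h replicate 2 and 1.24 in injured 12 h replicate 2, against -0.09 in the highest sham. These are the 2 arrays with the widest spread over genes.

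Fewer than 20 splits of 3 arrays against 3 exist, so the 10 splits of each comparison are too few for a share under 0.05. The real split gave 83 genes at 3 h with at most 0 in the others, 379 at 6 h with at most 0, and 692 at 12 h with at most 2. From 3 to 6 h the real split gave 170 and the highest other 0, from 6 to 12 h 2 and 2, and from 12 to 48 h 2180 and 61. For injury averaged over 3, 6 and 12 h, 1 of the 64 splits within time gave as many as 273 genes, the real one itself, and the highest other gave 1. That share is under 0.05, which makes chance unlikely there but does not exclude it. Every other split counts injured arrays as shams, which widens the spread of responding genes, so low counts were likely in advance. Other splits of 3 against 3 mix the groups likewise.

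The 48 h sham lay above the earlier shams in immediate early, cell cycle, complement and reactive astrocyte genes, though these calls were lost with an estimated correlation (adjusted p of 0.23, 0.41, 0.41 and 0.56) and 0 genes were called higher in the 6-group limma fit (973 at an unadjusted p under 0.05 in either direction), against 63 with only the groups compared and 21 with quantile normalization. Injury at 48 h gave 0 genes in limma against it (1061 at an unadjusted p under 0.05) and 1377 against the earlier shams. Against an exchange of labels with injured 48 h replicate 3 speak Lcn2 (5.47 in replicate 3, 1.79 in the sham) and Idi1 (-0.88 and 0.27). So do the medians of cholesterol synthesis (-0.51 and -0.06) and microglia markers (1.04 and 0.32). Lower in replicate 3 than in the sham, however, were Ccl2 (0.38 and 1.91), S100a9 (0.08 and 1.37) and Cdk1 (1.21 and 1.66). The medians of cell cycle genes (0.508 and 0.607) and reactive astrocyte genes (0.645 and 0.873) also went that way. An exchange therefore stays open. Over the 200 genes highest in the other injured 48 h arrays, replicate 3 exceeded the sham by a median of 0.117. Replicate 3 was higher in 60% of them. A shift common to the 48 h arrays is consistent with a correlation across genes of 0.338 between the 48 h sham's difference and the injured change from 12 to 48 h, but a batch and a true effect of time cannot be told apart with 1 array. An injury-like response to surgery was tested as the smallest gap between genes raised and lowered at 12 h. That gap was -0.033 with a bootstrap SE of 0.208, within its spread. Genes lowered at 12 h were also higher in the 48 h sham, where such a response would have lowered them. Their medians were 0.353 to 0.452, against 0.42 to 0.56 for raised genes. The bootstrap resamples genes of 1 array and not animals, so the question stays undecided.

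Ttr lay 5.24 and 6.06 above the early shams in injured 3 h replicates 2 and 3 and 5.57 in injured 12 h replicate 3. A response to injury that varies between animals stays open, since the range within groups, 4.63 at 3 h and 5.38 at 12 h, only restates the pattern, and 3 h replicate 1 and 12 h replicate 1 also lay above the shams, by 1.43 and 2.05. The choroid plexus genes Sostdc1 (1.90, 2.37 and 2.25) and Enpp2 (0.82, 1.35 and 1.26), whose values were seen first, were also high in these arrays. Choroid plexus tissue in these samples may explain the high Ttr. Against the other arrays of the same groups, 22 further choroid plexus genes had a median difference of 0.108. That was above the 95th percentile of random lists (0.058), although 12 lay above 0, with Cldn2, F5 and Mfrp over 1, and 9 below 0. At 3 h the only other array was replicate 1, so the differences of replicates 2 and 3 both rest on it. The random lists also treat genes as independent. Removing these arrays gave 14 genes at 3 h, where 1 injured array was left, and 1230 at 12 h.

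The neutrophil list was called higher at 6 and 12 h, with 3 and 4 of 9 genes called, in arrays where Hbb was higher as well, and both calls were lost with an estimated correlation (adjusted p = 0.087 each). From 3 to 6 h the mean of the 9 genes changed by 1.152 ± 0.43 more than Hbb did (1.64 against 0.48), but this rests on S100a9, S100a8 and Il1r2, while the other 6 averaged 0.33 and the median of all 9 was 0.60. Blood left in the tissue therefore stays open for the list, though Hbb was already 3.40 above the shams at 3 h, when S100a9 and S100a8 were not called, and the animals were perfused with saline. Leukocytes that entered the tissue and local expression of the same genes were not tested.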

How the results depend on the processing

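Robust eBayes, the fits without arrays high in Ttr or wide in spread, and the averaged comparison without each injured array were chosen only after the data were seen, when the probe set with the highest mean also changed from first choice to alternative. Of 2712 alternative values for 202 named gene results, 2382 kept the side of the threshold, 298 lost the call, 29 gained it and 3 reversed. Within the 2382, called genes also kept their direction, while genes not called either way could change sign. Of 840 alternative values for 64 list calls, 720 kept direction and call, 117 lost the call and 3 reversed. With an estimated correlation 9 of 64 list calls held. Median centring left all 9 counts within 1.5 times.

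Quantile normalization gave 199 genes at 3 h (134 higher, 65 lower), 921 at 6 h, 4 at 48 h, 29 for the 48 h sham, 706 from 3 to 6 h, 8 from 6 to 12 h, 1260 from 12 to 48 h and 429 averaged (272 higher, 157 lower); the cause was not tested. A 2-fold minimum, which can only remove genes, gave 49, 160 and 208 at 3, 6 and 12 h, 51 from 3 to 6 h, 288 from 12 to 48 h and 110 averaged. With only the groups compared in the fit, and so fewer arrays to estimate the spread, there were 151, 796, 271 and 1 at 3, 6, 12 and 48 h, 70 for the 48 h sham, 551 from 3 to 6 h, 0 from 6 to 12 h and 388 from 12 to 48 h. The single sham of the same hour, 1 control in place of 3, gave 13, 75 and 91.

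At 48 h the highest-mean probe set and every probe set tested gave 3 genes each and robust eBayes gave 1; the cause was not tested. The 3 earlier shams as control gave 1377 (905 higher, 472 lower), all 4 shams 963 and all 4 without the widest arrays 250. The replicate block gave 79 from 3 to 6 h. The difference of the injury effects, which adds the error of a lone sham, gave 29 from 12 to 48 h, and the fit without the widest arrays 967. Averaged injury gave 117 without a time factor and 137 with all 16 arrays. Without the arrays highest in Ttr there were 14 at 3 h and 1230 at 12 h. The cause was not tested for the block, the averaged fits or the Ttr arrays.

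Leaving out each array in turn gave 33 to 117 genes at 3 h, 177 to 274 at 6 h, 287 to 1230 at 12 h, 1 to 129 at 48 h, 0 to 2 for the 48 h sham, 39 to 157 from 3 to 6 h, 1 to 45 from 6 to 12 h, 1339 to 2442 from 12 to 48 h and 62 to 448 averaged. Of the named called genes, 17 of 24 at 3 h, 30 of 41 at 6 h and 31 of 48 at 12 h were called in every such fit. Those lost in at least 1 include Atf3, Col1a2, Idi1 and Serping1 at 3 h, Abcg2, Slco1a4 and Col3a1 at 6 h, and Gfap, Hmox1, Sele and Pvalb at 12 h.

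Fos reversed with the highest-mean probe set, to -0.15 at 3 h and -0.05 at 12 h, because its 2 probe sets disagree. Against the earlier shams Fos at 48 h was 0.56, and immediate early genes at 48 h had a median of 0.46, with all 4 shams 0.23 and with all 4 but without the widest arrays 0.175, since they were high in the 48 h sham. Arrays of the same replicate number did not pair, with correlations from -0.19 to 0.26. A filter on dim genes, an intensity trend and a mean of linear values were not run, since the centred values hold no signal over background.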

Other observations

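The comparisons of this part were chosen only after the values were seen, and no explanation was tested.

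Markers of the endothelium moved both ways at 6 h, which the list median of -0.17 hides. The tight junction genes Cldn5 (-1.52 ± 0.17, adjusted p = 0.000209) and Ocln (-1.03 ± 0.10), the angiopoietin receptor gene Tek (-1.41 ± 0.19) and the efflux pump gene Abcb1a (-1.18 ± 0.25) fell, while the VEGF receptor gene Flt1 (0.69 ± 0.15) and the adhesion gene Esam (0.47 ± 0.11) rose. Ocln was lower already at 3 h (-0.63 ± 0.10, adjusted p = 0.0106). At 12 h Cldn5 (-0.85 ± 0.17), Ocln (-0.78 ± 0.10) and Abcb1a (-0.94 ± 0.25, adjusted p = 0.047) were still lower and the VEGF receptor gene Kdr was higher (0.64 ± 0.14). At 48 h none of these differed from the 48 h sham in the test, with Cldn5 at 0.03 ± 0.24.

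Of the microglial markers, P2ry12, Gpr34 and Tmem119 (-1.22 ± 0.31, adjusted p = 0.0367) were lower at 12 h, while Tyrobp (0.95 ± 0.33, adjusted p = 0.12), Itgam (0.94 ± 0.31, adjusted p = 0.1) and Cd68 (0.77 ± 0.45, adjusted p = 0.37) had positive differences that did not pass.

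Injured 48 h arrays lay apart in Ccl2 and S100a9 but not in Lcn2. Ccl2 lay 3.59, 4.58 and 0.38 above the early shams in replicates 1, 2 and 3 and 1.91 in the 48 h sham. S100a9 lay at 0.79, 3.86 and 0.08, and at 1.37 in the 48 h sham. Lcn2 lay at 5.47, 5.92 and 5.47, and at 1.79 in the 48 h sham.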
